A study of Mus musculus with 6 samples.

How the data were processed

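Gene expression was measured by 3′ mRNA sequencing in 6 libraries of the mouse macrophage-like line RAW264.7. Per the labels, 3 libraries came from untreated cells (control) and 3 from cells exposed to itaconate for 24 h. The RNA was extracted with TRIzol and made into libraries with the Lexogen QuantSeq FWD kit, per the labels' protocols. That kit primes on the poly(A) tail, so a read falls near the 3′ end of a transcript and transcript length carries less weight than in whole-transcript libraries. The labels give neither the dose nor the form of the itaconate (acid or derivative). The control label reads no treatment, and no vehicle is named. The labels also do not say whether the libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Each group was assigned from the treatment label. The library numbers in the titles run on from the control group into the itaconate group, and no batch or date is named, so no comparison within batches could be made.

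The deposited values are raw counts of reads per gene symbol, made by the authors and not normalized. The submitters' processing notes name STAR 2.7.5a, HTSeq 0.6.1, edgeR and the genome build mm10. Read trimming, the strand setting, the treatment of reads that map to several places and the annotation version are not given in the sources used here. The header line of the count table is separated by tabs and holds 2 empty cells, while the data lines are separated by spaces, so the 6 count columns were taken in the order of the 6 names in the header, which name the groups and replicates. All 6 of the 6 count columns were used, and 0 columns belonged to another series. The table holds 35976 symbols, of which 17720 had a count in at least 1 library. Mitochondrial genes are listed under their short names (ND1, COX1, CYTB and others) and were matched to the lists by those names.

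The library totals ran from 5202626 to 6098934 counts, so the floor of 3 counts per library corresponds to between 0.492 and 0.577 CPM (counts scaled to a common library total). The floor covers counting error only, since reads without molecular identifiers are not independent molecules. Where a gene had 0 counts in every library of a group, its fold was given as a lower bound against 3 counts over the whole group. Genes were kept with the default settings of edgeR's filterByExpr (a minimum count of 10 and a minimum total of 15), which left 10636 genes holding 99.74% of all counts. Libraries were scaled by TMM. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, robust dispersion) with the group as the only term, on all 6 libraries, two-sided, with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. Fold changes are log2 of itaconate over control with their standard errors (SE). The SE was taken as the absolute log2 fold change divided by the square root of the F statistic. CPM values are TMM-scaled means with SD over 3 libraries.

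Before the data were examined, 33 gene lists with 734 genes were fixed, of which 729 genes were found in the table. They cover NRF2 targets, the integrated stress response (ATF4), interferon-stimulated genes, NF-kB inflammatory genes, alternative activation, itaconate synthesis and handling, glycolysis, the TCA cycle, the nuclear-encoded respiratory chain, mitochondrially encoded transcripts, cholesterol and fatty acid synthesis, LXR targets, lysosome, autophagy, S phase, G2 and mitosis, p53 targets, hypoxia, heat shock and chaperones, the ER unfolded protein response, iron and metal handling, MHC presentation, osteoclast differentiation, macrophage identity, ribosomal proteins, the proteasome, nuclear-retained and immediate-early transcripts, and markers of fibroblasts, T and NK cells, B cells, neutrophils and mast cells, and epithelium. The 28 lists with at least 5 tested members were tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists. Each list's called members were also counted with the p adjusted over the list alone.

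The genes named were chosen by a rule fixed at the same time. It takes the 12 largest rises and the 12 largest falls among called genes with a mean of at least 5 CPM and with every itaconate library on the same side of every control library, leaving out unnamed and predicted genes. It adds the 4 members with the smallest p from each list that passed or held at least 3 called members, up to 2 members from each other list, and every tested member of the itaconate list. The rule gave 132 genes, of which some are not reported here. A gene whose values are given outside the rule is said to be chosen after its values were seen.

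Coordinates come from the RefSeq annotation of GRCm38.p6, the assembly that mm10 names, in which 90.3% of the symbols of the table were found. Overlaps with exons of other genes were taken from GENCODE M21, for the last 500 exonic nt of each gene's longest transcript. There, 3 of the named genes overlap another gene on the same strand and 9 a gene on the opposite strand. Their counts are uncertain because the strand setting is not stated. The 4 named genes not found in GENCODE M21 (D17H6S56E-5, Fam64a, ND4 and COX1) could not be checked. The last 500 nt of each list gene's longest transcript were also searched in steps of 10 nt for stretches of 50 nt that occur in a transcript of another gene. Among the 128 named genes that could be searched, 9 shared at least 20% of those stretches (among them Ccna2, Csf1r, Ftl1, Lpcat3, Mcm7, Psmd1, Rps29 and Sqstm1), and reads of these genes may have been lost or assigned to the other gene.

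The alternatives comprised DESeq2 size factors, upper-quartile scaling and library totals in place of TMM, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, edgeR without robust dispersion, the replicate number as a block, thinning to the smallest library, leaving out each library in turn, stricter thresholds, camera with an estimated correlation, and limma's fry. A loess offset for GC content and transcript length was added after the data had been seen. Simulated counts for the 10636 genes of the itaconate comparison, with 200 genes changed, were tested with the same code. It recovered 27% of the genes changed by 1.5-fold and 91% of those changed by 2-fold, with 1.6% of its calls false, and called 0 of 20 lists without a change. The simulation used 1 dispersion for all genes and took the 200 genes from those with a mean of at least 5 CPM. Its shares therefore do not describe each real gene. A further list was shifted by 0.5 on the log2 scale. The changed share was far smaller than the 21.9% of genes called in the data. Genes were drawn independently, so the 20 lists do not show how often camera errs when list members move together.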

Results

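RAW264.7 cells, a mouse line with macrophage properties, were left untreated or exposed to itaconate for 24 h, and their polyadenylated RNA was counted by 3′ sequencing in 3 libraries per group. Itaconate is a dicarboxylate that activated macrophages make in mitochondria from the TCA cycle intermediate cis-aconitate, through the enzyme encoded by Acod1. The libraries held 5202626 to 6098934 counts. Log2 CPM values correlated across genes at 0.963 to 0.970 (Pearson) between libraries of the same group and at 0.930 to 0.934 between groups, and the first dimension of a multidimensional scaling, with 51.5% of the variance, separated the groups. Replicate libraries of each group differed by more than binomial sampling of reads at their library totals, with a chi-square per gene of 4.77 to 7.49. Reads without molecular identifiers are not independent molecules, which can also raise this value, so it does not show a difference between cultures. Mitochondrial transcripts took 4.81% ± 0.444 of counts in control and 5.04% ± 0.375 in itaconate libraries (SD, n = 3, exact two-sided permutation p = 0.5). That share rests on 7 of the 13 mitochondrial genes, since COX2, COX3, ATP6, ATP8, ND3 and ND4L had at most 5 counts over either group. The 10 most abundant genes of each library took 9.22% ± 0.386 and 10.5% ± 0.160 (SD, n = 3, exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give).

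The comparison asked which transcripts differ after exposure to itaconate. Itaconate-exposed cells had far more transcript from NRF2 target genes, including Gclm, Slc7a11, Srxn1 and Cat. They had less transcript from genes of DNA replication and mitosis, from interferon-stimulated genes and from NF-kB inflammatory genes. The lists of ATF4-dependent stress, glycolytic, lysosomal and iron-handling genes also passed as higher, with 20 of 29, 11 of 21, 17 of 33 and 5 of 16 members rising, but not with an estimated correlation (adjusted p = 0.0564, 0.128, 0.122 and 0.119). Acod1 itself fell from 12.9 ± 2.85 CPM to 1.03 ± 0.252 CPM (SD, n = 3). Of 10636 genes tested, 1133 were higher and 1191 lower at an adjusted p under 0.05, together 21.9%, and 256 of the higher and 411 of the lower genes changed by at least 1 on the log2 scale. Among the called genes, all itaconate libraries lay above all control libraries for 1083 and below them for 1140. Such separation was seen in 35.6% of all tested genes, against 10% by chance.

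**Figure D1:**
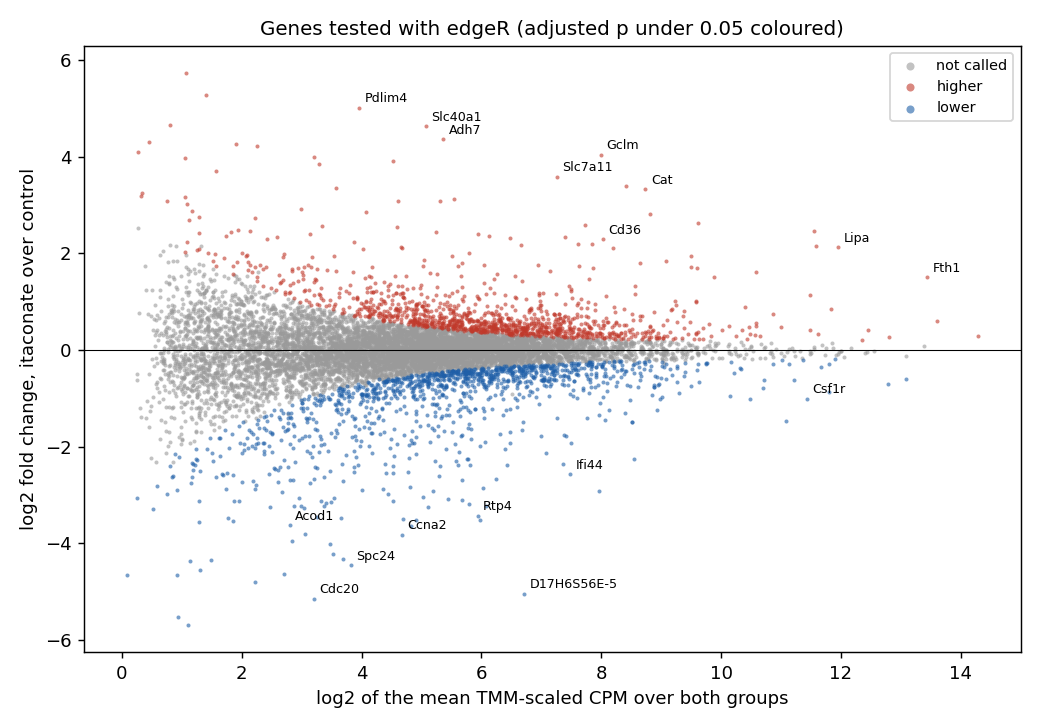
Log2 fold change (itaconate over control) of each tested gene against the log2 of its mean TMM-scaled CPM, with called genes coloured and a few named. Genes with 0 counts in a whole group are left out; Gclm (log2 fold change 4.04) and D17H6S56E-5 (-5.03) stand far from 0 at moderate to high counts.

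Among the genes that met the naming rule, Pdlim4, which encodes a cytoskeletal PDZ and LIM domain protein, rose most, by 5.01 ± 0.36 on the log2 scale (SE, edgeR adjusted p = 4.18e-16), from 0.917 to 30.2 CPM. Slc40a1, the iron exporter ferroportin, rose by 4.63 ± 0.26 and the alcohol and retinol dehydrogenase gene Adh7 by 4.35 ± 0.22. Next came Gclm, the modifier subunit of glutamate-cysteine ligase, with a rise of 4.04 ± 0.12 (adjusted p = 2.94e-31). Gclm lies on chromosome 3 from 122245487 to 122267215 and went from 29.4 ± 6.26 to 481.9 ± 20.2 CPM (SD, n = 3). The others of the 12 were the phosphatase gene Ptpn14 (3.98), the protein C receptor gene Procr (3.90), Gadd45g (3.85), the cystine transporter gene Slc7a11 (3.58), the sulfiredoxin gene Srxn1 (3.40), Serpinb9b (3.34), the catalase gene Cat (3.33) and Clec4n (3.13), which encodes the lectin receptor Dectin-2. The falls were led by Cdc20, the activator of the anaphase-promoting complex, at -5.14 ± 0.52, whose exons overlap Elovl1 on the opposite strand. D17H6S56E-5 fell from 203.9 to 6.17 CPM (log2 fold change -5.03 ± 0.17, adjusted p = 5.88e-28). The kinetochore genes Spc24 (-4.45) and Nuf2 (-4.00), the replication factor gene Mcm10 (-4.21), and the cyclin genes Ccna2 (-3.82) and Ccnb2 (-3.65) followed, with Sapcd2 (-4.64), Fam64a (-4.31), Shcbp1 (-3.95) and Acod1 (-3.62). The exons of Ccna2 overlap Exosc9 on the opposite strand.

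Targets of NRF2, the transcription factor of the oxidative and electrophile stress response, moved together. Of 27 tested, 26 rose and 1 fell, with the same counts when adjusted over the list alone, and the median log2 fold change was 2.01 (camera adjusted p = 1.73e-27, and 0.00649 with an estimated correlation). Besides Gclm, Srxn1 and Cat, the biliverdin reductase gene Blvrb rose from 112.1 ± 6.73 to 791.4 ± 91.7 CPM (SD, n = 3). The member that fell was Nfe2l2, which encodes NRF2 itself, at -0.25 ± 0.09 (chosen after its values were seen). Nqo1, also chosen after its values were seen, had 0 counts in the control group and was at least 28.2-fold higher in the itaconate group. With Nqo1 at that bound, the list median stayed at 2.01.

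In the integrated stress response list, the genes induced through ATF4, 20 of 29 rose, 0 fell and 9 were not called, and 22 rose when adjusted over the list alone. The median was 0.59 (camera adjusted p = 2.76e-10, and adjusted p = 0.0564 with an estimated correlation). Trib3, a pseudokinase gene, rose by 1.57 ± 0.13, Atf5 by 1.33 ± 0.10, Slc3a2, the heavy chain shared by amino acid transporters, by 1.15 ± 0.09 and the asparagine synthetase gene Asns by 0.95 ± 0.09. The heat shock and chaperone list had 0 called members of 15 with edgeR (0 over the list alone, 2 at an unadjusted p under 0.05), with a median of -0.06 and camera adjusted p = 0.853. Its member Bag3 was called higher by limma-voom, without control replicate 3 (edgeR adjusted p = 0.0402) and with an offset for GC content and length (0.0344), and Hspa4l without itaconate replicate 3 (0.027) and with that offset (0.0463), while DESeq2 called 0 members. In the ER unfolded protein response list 2 of 20 rose and 1 fell (1 and 1 over the list alone, adjusted p = 0.575). Sel1l rose by 0.43 and the calreticulin gene Calr fell by 0.30 on the log2 scale.

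Replication and division genes fell. In the S phase list 25 of 27 fell, 0 rose and 2 were not called (26 lower over the list alone), with a median of -1.69 (camera adjusted p = 2.8e-18, and 0.0293 with an estimated correlation). Subunit genes of the replicative helicase were among them: Mcm5 at -2.40 ± 0.19, Mcm7 at -2.37 ± 0.15, Mcm6 at -2.04 ± 0.17 and Mcm3 at -1.69 ± 0.13. Mcm7 exons overlap Cops6 on the opposite strand. In the G2 and mitosis list all 29 tested members fell (29 over the list alone), with a median of -2.35 (adjusted p = 1.73e-27, and 0.0163 with an estimated correlation). Top2a, the topoisomerase that untangles replicated DNA, went from 275.4 ± 15.9 to 53.9 ± 6.53 CPM (SD, n = 3), Birc5, or survivin, fell by 3.51 ± 0.17 on the log2 scale, and the mitotic kinase gene Plk1 fell by 3.24 ± 0.21. The p53 target list was not called (adjusted p = 0.847), with 4 of 18 higher and 3 lower (the same over the list alone). The stress cytokine gene Gdf15 rose by 1.94 ± 0.33 and the pro-apoptotic Pmaip1 fell by 0.98 ± 0.19 on the log2 scale.

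**Figure D2:**
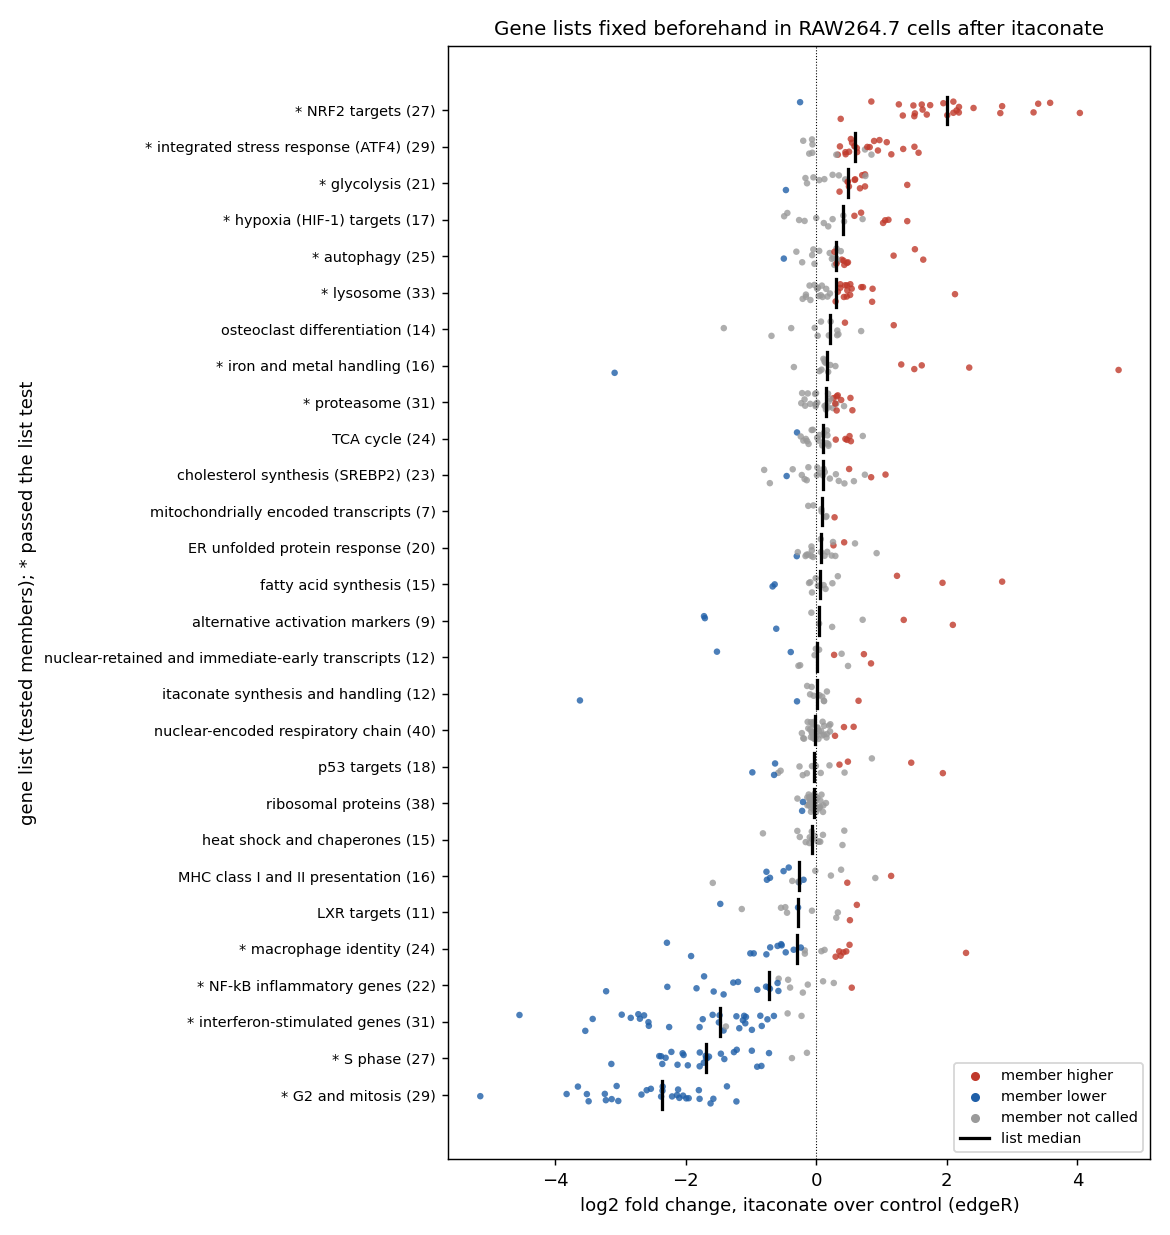
Log2 fold change (itaconate over control) of each tested member of the 28 lists tested, coloured by its call, with the list median as a bar and an asterisk on the 13 lists that passed the list test. Nqo1 and C1qb, with 0 counts in a whole group, are not drawn; list medians run from -2.35 (G2 and mitosis) to 2.01 (NRF2 targets).

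Interferon-stimulated genes fell in the itaconate group: 28 of 31 were lower, 0 higher and 3 not called (29 lower over the list alone), with a median of -1.48 (camera adjusted p = 6.9e-18, and 0.0293 with an estimated correlation). Log2 fold changes were -3.42 ± 0.17 for Rtp4, -2.84 ± 0.22 for Oas2, an antiviral oligoadenylate synthetase gene, -2.57 ± 0.11 for Ifi44 and -2.25 ± 0.16 for Irf7, a master transcription factor of the interferon response. Of 22 tested NF-kB inflammatory genes, 14 fell, 1 rose and 7 were not called (16 lower and 1 higher over the list alone), with a median of -0.72 (adjusted p = 8.53e-06, and 0.0471 with an estimated correlation). The chemokine gene Cxcl2 had a log2 fold change of -3.22 ± 0.44, the cytokine gene Tnf of -1.57 ± 0.20, Marcksl1 of -1.27 ± 0.16 and Nfkbia, the NF-kB inhibitor, of -0.73 ± 0.08. The member that rose was the chemokine gene Ccl3 (0.55, chosen after its values were seen). In the MHC presentation list 2 of 16 rose and 7 fell (3 and 7 over the list alone), and the list was not called (adjusted p = 0.325). Cd74, the invariant chain, and the immunoproteasome genes Psmb9 and Psmb10 had log2 fold changes of -0.76, -0.71 and -0.75. The class I gene H2-D1 rose by 1.15 ± 0.07, a value that is uncertain because H2 genes are close paralogs and RAW264.7 comes from another strain than the reference.

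Macrophage identity genes went both ways, with 13 of 24 lower, 7 higher and 4 not called (the same over the list alone) and a median of -0.29, also with C1qb at its bound. The list passed as lower (camera adjusted p = 0.025), but not with an estimated correlation (adjusted p = 0.398), without control replicate 1 (0.0537), without itaconate replicate 1 (0.053) or with a stricter filter (0.0803). Over the 11 other fits with the preset correlation, the adjusted p ran from 0.011 to 0.0803. Csf1r, the receptor of the growth factor M-CSF, had a log2 fold change of -1.01 ± 0.07, the lipopolysaccharide co-receptor gene Cd14 of -0.96 ± 0.08 and the transcription factor gene Maf of -2.28 ± 0.20, while the scavenger receptor gene Cd36 rose by 2.30 ± 0.10. Csf1r exons overlap Hmgxb3 on the opposite strand. C1qb, a complement gene chosen after its values were seen, had 0 counts in the itaconate group and was at least 28.8-fold lower. The alternative activation list was not called (adjusted p = 0.921), with 2 of 9 higher, 3 lower (the same over the list alone). Its transglutaminase gene Tgm2 rose by 2.09 ± 0.27, and the mannose receptor gene Mrc1 fell by 1.70 ± 0.24 on the log2 scale. In the osteoclast list 2 of 14 rose and 0 fell (the same over the list alone, adjusted p = 0.285), the proton pump genes Atp6v0d2 (1.19) and Tcirg1 (0.44).

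In the glycolysis list 11 of 21 rose, 1 (Pfkl, chosen after its values were seen) fell and 9 were not called (12 and 1 over the list alone), with a median of 0.48 (camera adjusted p = 0.000188, and adjusted p = 0.128 with an estimated correlation). Counts of some members are uncertain because other genes share the searched stretches of their 3′ ends. Such members, chosen after their values were seen, include Gapdh (89.1%) and Eno1 (73.9%), not called, and Pfkp (100%), called higher. The glucose transporter gene Slc2a1 rose by 1.40 ± 0.15, the hexokinase gene Hk2 by 0.75 ± 0.11, the aldolase gene Aldoa by 0.75 ± 0.07 and the lactate carrier gene Slc16a3 by 0.67 ± 0.10. Hypoxia (HIF-1) targets had 6 of 17 higher and 0 lower (7 over the list alone), a median of 0.42 and adjusted p = 0.00545 (adjusted p = 0.116 with an estimated correlation). Besides Slc2a1, which both lists hold, the lipid droplet gene Hilpda rose by 1.11 ± 0.13, Ero1l by 1.06 ± 0.15 and Ndrg1 by 0.69 ± 0.10. The TCA cycle list was not called (adjusted p = 0.312), with 5 of 24 higher and 1 lower (the same over the list alone), among them the oxoglutarate dehydrogenase gene Ogdh (0.53 ± 0.10). In the nuclear-encoded respiratory chain 3 of 40 rose and 0 fell (2 over the list alone, adjusted p = 0.601), with Uqcrq at 0.57 ± 0.08, and 1 of 7 mitochondrially encoded transcripts was called higher (1 over the list alone, adjusted p = 0.56). It was ND4 (0.28 ± 0.08), whose libraries overlapped between the groups. Its call was lost with DESeq2 (adjusted p = 0.224), with library totals (0.0992) and without control replicate 3 (0.098), itaconate replicate 1 (0.104) or itaconate replicate 3 (0.0503).

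Of 12 tested genes that make, carry or respond to itaconate, 1 rose, 2 fell and 9 were not called (the same over the list alone, camera adjusted p = 0.801). Acod1, on chromosome 14 from 103047012 to 103056573, fell by 3.62 ± 0.47 on the log2 scale (edgeR adjusted p = 2.19e-08). The citrate carrier gene Slc25a1 rose by 0.65 ± 0.17. Sdha, the catalytic subunit of succinate dehydrogenase, which itaconate inhibits, was lower by a small margin (-0.29 ± 0.09, adjusted p = 0.0167), a call lost without control replicate 2 (0.0713), control replicate 3 (0.07) or itaconate replicate 2 (0.071). The other subunits were not called, with log2 fold changes of -0.14 ± 0.08 for Sdhb, 0.17 ± 0.10 for Sdhc and 0.12 ± 0.63 for Sdhd. Clybl, whose enzyme degrades a product of itaconate, had -0.04 ± 0.17, and the succinyl-CoA synthetase genes Suclg1, Sucla2 and Suclg2 had 0.09, 0.05 and -0.07. The carriers Slc25a10 and Slc25a11 had -0.09 and 0.12.

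Lysosomal genes rose, with 17 of 33 higher, 0 lower and 16 not called (17 higher and 1 lower over the list alone) and a median of 0.30 (camera adjusted p = 4.05e-05, and adjusted p = 0.122 with an estimated correlation). Lipa, the lysosomal acid lipase, went from 1480 ± 93.7 to 6463 ± 598 CPM (SD, n = 3), and the protease genes Ctsd and Ctsl rose by 0.86 ± 0.07 and 0.54 ± 0.08. In the autophagy list 10 of 25 rose, 1 (Uvrag, chosen after its values were seen) fell and 14 were not called (the same over the list alone), with a median of 0.31 (adjusted p = 0.000958, and adjusted p = 0.122 with an estimated correlation). Sqstm1, the cargo receptor p62, which the NRF2 list also holds, rose by 1.51 ± 0.08, and Gabarapl1 and Map1lc3b, of the LC3 family, rose by 1.19 ± 0.11 and 0.49 ± 0.11. Proteasome genes had 8 of 31 higher and 0 lower (8 over the list alone), a median of 0.16 and adjusted p = 0.029, led by the regulatory particle genes Psmd11 (0.56) and Psmd7 (0.52). That call was lost with an estimated correlation (adjusted p = 0.478), without control replicate 2 (0.0735), without control replicate 3 (0.101) and without itaconate replicate 3 (0.0758). Over the 11 fits, the adjusted p ran from 0.0149 to 0.101.

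Iron and metal handling genes had 5 of 16 higher, 1 lower (the ferroxidase gene Cp, chosen after its values were seen) and 10 not called (the same over the list alone), with a median of 0.17 (camera adjusted p = 0.00799, and adjusted p = 0.119 with an estimated correlation). The ferritin genes Fth1 and Ftl1, which the NRF2 list also holds, rose, Fth1 from 5793 ± 345 to 16420 ± 664 CPM (SD, n = 3) and Ftl1 by 1.62 ± 0.08 on the log2 scale. Ftl1 shares 82.6% of the searched stretches of its 3′ end with other genes. The phagosomal metal transporter gene Slc11a1 rose by 2.34 ± 0.12. Without the members that the NRF2 list holds, 3 of 14 were higher and 1 lower.

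**Figure D3:**
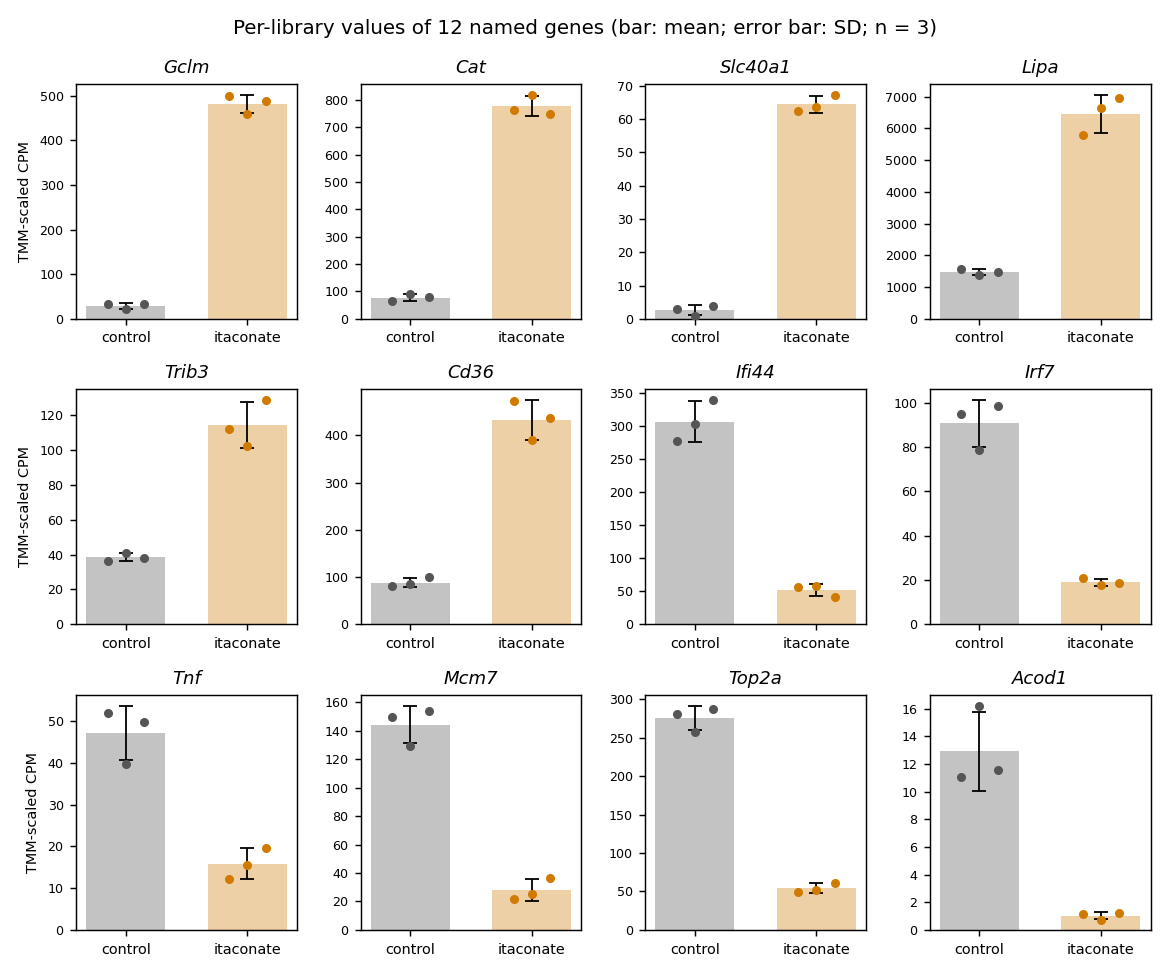
TMM-scaled CPM of 12 named genes in each library (points), with the mean (bar) and SD (error bar) of the 3 libraries per group, on linear axes from 0. In each panel the 3 itaconate libraries lie on one side of the 3 control libraries, as for Gclm at 29.4 against 481.9 and for Acod1 at 12.9 against 1.03. The naming rule required this separation of Gclm, Cat, Slc40a1 and Acod1, and the others are members of their lists with the smallest p, so it is no separate result.

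Lipid lists were not called. Cholesterol synthesis had 3 of 23 higher and 1 lower (2 and 1 over the list alone, camera adjusted p = 0.474), with Ebp at a log2 fold change of -0.45 ± 0.12. Fatty acid synthesis had 3 of 15 higher and 2 lower (4 and 2 over the list alone, adjusted p = 0.285): the malic enzyme gene Me1 (2.85), Acss2 (1.94) and the desaturase gene Scd1 (1.24) rose, and the fatty acid synthase gene Fasn (-0.64) and Elovl6 (-0.67, chosen after its values were seen) fell. LXR targets had 2 of 11 higher and 2 lower (the same over the list alone, adjusted p = 0.638), with the cholesterol exporter gene Abca1 at -1.47 ± 0.27 and Smpdl3a at 0.52 ± 0.11. Of 38 ribosomal protein genes 0 rose and 2 fell with edgeR, Rps9 and Rps29 (0 over the list alone, 4 at an unadjusted p under 0.05, adjusted p = 0.601). Counts of several ribosomal genes are uncertain because other genes share most of the searched stretches of their 3′ ends. Rps6 and Rpl13, chosen after their values were seen, share 89.1% each. Of the fits with a library left out, the call of Rps29 was lost without control replicate 1, control replicate 2 or itaconate replicate 2 (edgeR adjusted p of 0.102 to 0.152), and that of Rps9 without control replicate 1 or 3 or itaconate replicate 1 or 2 (0.109 to 0.251). The nuclear-retained and immediate-early list had 3 of 12 higher and 2 lower (the same over the list alone, adjusted p = 0.768), with Ier3 at 0.84, Egr1 at 0.73 and Fos at -1.52. Markers of other cells were near the floor: 1 fibroblast, 1 T or NK cell and 1 neutrophil or mast cell gene could be tested (Acta2, Lck and Csf3r, not called), and 0 B cell and 0 epithelial genes. Their summed levels in control and itaconate libraries were 6.08 and 4.89 CPM for fibroblasts, 3.01 and 5.54 for T and NK cells, 0 and 0.585 for B cells, 5.49 and 5.55 for neutrophils and mast cells, and 0.577 and 0.309 for epithelium.

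Of the 28 lists tested, 13 passed, 8 as higher and 5 as lower, and 5 passed with an estimated correlation: NRF2 targets, interferon-stimulated genes, NF-kB inflammatory genes, S phase, and G2 and mitosis. With 3 libraries per group and no stated dose or form of itaconate, the values describe 1 exposure at 1 time.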

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

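Apart from the GC and length offset, which was chosen after the data had been seen, the settings below were chosen before the results. With other scalings, filters and tools, the counts of higher and lower genes stayed within 1.5 times the 1133 and 1191 given above, from 936 and 1427 with library totals only to 1309 and 1061 with the offset for GC content and length, and DESeq2 gave 962 and 990, leaving the adjusted p of 5153 genes as NA. Of the genes called, 0 were called in the opposite direction under any of these settings. Leaving out each library in turn gave 882 to 1001 higher genes, 915 to 1102 lower genes and 12 to 13 lists, with fewer libraries in each fit. An adjusted p under 0.01 kept 744 higher and 784 lower genes, and a log2 fold change of at least 1 kept 256 and 411, as stricter thresholds must keep fewer. With an estimated correlation, 5 lists passed in place of 13, and that correlation comes from few residual degrees of freedom. It was below the preset 0.01 for NRF2 targets (-0.001), NF-kB genes (0.008), iron handling (-0.043) and hypoxia (-0.059). For the other called lists it was 0.035 to 0.118. The adjusted p rose for the lists below 0.01 as well, so a call lost this way does not show that members move together. The limma test fry, which does not compare a list with other genes, called 15 lists, adding the TCA cycle (adjusted p = 0.0223) and fatty acid synthesis (adjusted p = 0.000798). Apart from macrophage identity and proteasome, the called lists had adjusted p of at most 0.0272 over the 11 other fits with the preset correlation. Replicate numbers share no stated origin: deviations of same-numbered libraries correlated at 0.01, 0 and 0.076. A replicate block gave 1087 higher genes, 1160 lower genes and 13 lists. It kept 1070 of the 1133 higher and 1139 of the 1191 lower calls. Among the named genes it ended the calls of Ndufa1 (edgeR adjusted p = 0.0587), Pmvk (0.0659) and Rps9 (0.0617). Of the 132 named genes, 115 were called. Stricter thresholds aside, 101 of these kept the call in every fit that tested them, 14 lost it in at least 1, and 0 reversed; the stricter filter tested 129 of the 132 and the offset 128. The cause of these losses was not tested; the genes were Mgl2, Klf4, Sdha, Cs, Ndufa1, ND4, Sc5d, Pmvk, Lpcat3, Abcg1, Pdia6, Rps29, Rps9 and Malat1. Where edgeR called 0 members of a list in a direction, limma-voom and DESeq2 also called 0, except 1 lysosome and 1 respiratory chain gene called lower by both, 1 ribosomal gene called higher by both, and 1 chaperone gene called higher by limma-voom. Of the 8312 genes not called, 3604 had a 95% interval (SE times a normal quantile) within a 1.5-fold change in either direction. For the others these data do not exclude a change of that size. With 3 libraries per group such intervals may be too narrow, so the 3604 may be too many.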

Other observations

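The 8 further gene lists below with the V-ATPase test, the genes named here, the offset for GC content and length, the splits of the libraries, the scaling test, the test of a shared control state and the chaperone test were chosen after the main results had been seen.

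Glutathione metabolism rose as a list, with 9 of 15 genes higher, 1 lower and 5 not called (10 and 1 over the list alone), a median log2 fold change of 1.59 and camera adjusted p = 7.32e-07 (adjusted p = 0.0461 with an estimated correlation). Of its members, 5 also belong to the NRF2 list, and among the other 10 there were 4 higher and 1 lower, with a median of 0.30. The esterase gene Esd rose by 2.63 and the glutathione synthetase gene Gss by 1.59, while the peroxidase gene Gpx1 fell by 1.48 on the log2 scale. The pentose phosphate list was not called (adjusted p = 0.264): 4 of 10 rose, all of which the NRF2 list also holds (Pgd, Taldo1, G6pdx and Tkt), and 3 fell (4 over the list alone), among them the phosphoribosyl pyrophosphate synthetase genes Prps1 (-0.44) and Prps2 (-0.77). Glycogen metabolism had 5 of 11 higher and 0 lower (the same over the list alone) and was not called (adjusted p = 0.059), with the branching enzyme gene Gbe1 up by 2.44 and Pgm2 by 1.15.

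Homologous recombination and Fanconi genes had 8 of 17 lower and 0 higher (10 lower and 1 higher over the list alone), a median of -1.03 and adjusted p = 2.45e-05 (adjusted p = 0.113 with an estimated correlation), with Bard1 at -2.09 and Brca1 at -1.41. Purine and pyrimidine synthesis had 6 of 18 lower and 0 higher (7 over the list alone), a median of -0.21 and adjusted p = 0.00527 (adjusted p = 0.143 with an estimated correlation), with the thymidine kinase gene Tk1 at -2.91 and Dtymk at -1.26. Surface receptors went both ways. Of 14 scavenger and C-type lectin receptors 5 rose and 5 fell (6 and 5 over the list alone, adjusted p = 0.574), with Clec4d at 1.79 and Clec12a at -1.76. Of 15 chemokine and adhesion receptors 3 rose and 5 fell (the same over the list alone, adjusted p = 0.677): the chemokine receptor gene Cxcr4 rose by 3.08 and the fractalkine receptor gene Cx3cr1 fell by 2.92 on the log2 scale.

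The S phase and G2 and mitosis lists fell together, with a pooled median log2 fold change of -2.04 over 56 genes. The other scalings between libraries left the pooled median no nearer 0 than -2.04, so the choice among them does not account for the fall. They differ little, with a median over all tested genes of -0.058 to -0.003, and cannot test a larger error of scale. GC content or transcript length as the whole cause is argued against by a pooled median of -2.00 with the offset. A single dividing control library is argued against by -1.98 as the value nearest 0 with any 1 library left out. Slower division of the exposed cells is a hypothesis that these values leave open, and cell number and growth rate were not analysed here. A difference in culture density between the groups was not tested.

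The interferon and NF-kB lists fell with a pooled median of -1.20 over 53 genes. The offset for GC content and length left it at -1.16, and leaving out any 1 library left it at -1.13 or further from 0, which argues against these trends or 1 activated control library as the whole cause. An activated state shared by the 3 control libraries and a repression by itaconate both predict the median of -1.20. They cannot be told apart, because no other untreated cells were measured and the labels do not say how the libraries of a group relate to cultures. Of 13 members with too few counts to test, 8 had fewer counts over the itaconate than over the control libraries, such as Cxcl10 (0 and 39), 2 had more, Ptgs2 (36 and 15) and Il1a (5 and 0), and 3 had none in either group.

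The NRF2 list rose with a median of 2.01 over 27 genes. The offset for GC content and length left the median at 1.97, which argues against that trend as the whole cause. A general proteotoxic stress could raise chaperone genes as well. The mean log2 fold change over the 15 tested chaperone genes was -0.05, with an upper 95% bound of 0.11. That bound treats the genes as independent and holds the spread between genes, not between libraries. The chaperone values were already known when the limit of 0.5 was set, so the bound describes that list and is no independent test. It lies below a mean rise of 0.5 at 24 h, and an earlier rise was not measured. A response limited to a few chaperones stays open, since Bag3 (0.44) and Hspa4l (0.49) were called higher with the same offset. An electrophile stress response to itaconate may account for the rise and is a hypothesis, since no inhibitor or NRF2-deficient cells were measured here.

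The rise of the lysosome list may extend to the proton pump that acidifies the lysosome. Of 18 V-ATPase subunit genes, 12 rose, 0 fell and 6 were not called (the same over the list alone), with a median of 0.34 (camera adjusted p = 7.36e-05, and adjusted p = 0.13 with an estimated correlation). Of these genes, 7 also belong to the lysosome or osteoclast lists, whose values had been seen, and of the other 11, 7 rose, with a median of 0.31.

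The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 1133 higher genes, 1191 lower genes and 13 lists, and it was the 1 split to reach each of these. The highest of the other splits gave 0 higher genes, 0 lower genes and 11 lists, and each of them called at least 5 lists. Each of these other splits puts libraries of both treatments in each group. The treatment difference then widens the spread within the groups, and part of it stays between them. They therefore cannot show what libraries without a treatment difference would give, and no conclusion is drawn from them.

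Gapdh was counted at 36.6 CPM in control libraries against 1396 for Aldoa, and 89.1% of the searched stretches of its 3′ end occur in transcripts of 129 other genes.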
